A study of Mus musculus with 2 samples.

How the data were processed

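Brains were dissociated, myelin was removed, and cells were enriched with anti-ACSA-2 beads, with about 10000 cells loaded per condition on a 10x Chromium chip with 3' v3 chemistry, per the labels' protocols. The deposited files hold UMI counts per gene and barcode, not normalized and not filtered, per the file contents: 55401 genes and 6794880 barcodes in each library, of which 1212435 in metastasis and 1051839 in naive have a UMI. Per the submitters' processing notes, the authors used STARsolo and GRCm38; the version, the annotation and the settings were not given in the sources used here. Of the 55401 gene identifiers, 54349 matched GENCODE M21 with their version and 55141 without it, and coordinates come from that annotation.

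A barcode was kept with at least 1000 UMIs, at least 500 genes and at most 20% of UMIs from mitochondrial genes. At least 1000 UMIs were found in 13937 and 14301 barcodes, more than the 10000 cells loaded, so some kept barcodes can be droplets with free RNA or debris. The gene limit removed 83 and 171 and the mitochondrial limit 109 and 135. Doublets were called per library with scrublet as implemented in scanpy 1.11.5 (expected rate 0.06, seed 0), which removed 405 (2.95%) and 889 (6.35%). Kept cells had medians of 1515 and 1468 genes and 2.27% and 2.75% mitochondrial UMIs.

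Cells of both libraries were clustered together without integration: UMIs scaled to 10000 per cell, log1p, 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1. A cluster was called "like" a cell type from 19 marker lists fixed before the data were examined. The thresholds for naming were set after the clusters had been seen. A list needed a median log2 fold of at least 1 and at least 3 members at 2-fold. The fold was that of the cluster over the unweighted mean of the other clusters, with 20 CPM added to both. No other list could have more markers among the 10 leading genes of the cluster, and no second list could be close behind. A cluster of low depth with no marker of its list among those 10 genes could also be left unnamed. These thresholds kept 4 clusters unnamed, with 4.75% of cells in metastasis and 6.01% in naive: cluster 16 (1.32% and 1.79%), cluster 17 (1.21% and 1.89%), cluster 18 (0.690% and 2.19%) and cluster 21 (1.54% and 0.145%). Cluster 17 lay nearest to the astrocyte list. Astrocyte-like cells were clusters 4 and 22. Classes are rebuilt from markers and can differ from the study's own.

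Counts were summed per gene over the cells of a class in each library and divided by the sum over all genes, on the usual scale of CPM, in classes with at least 50 cells in both libraries. Astrocyte-like cells held 617762 UMIs in metastasis and 1991872 in naive, and 10387 genes had at least 20 UMIs. Ratios have exact conditional binomial intervals and shares have exact Clopper-Pearson intervals, at 95%. A sum of 0 was set to the floor of 3 UMIs over the class, which gives a bound. Folds given as "at least" in this way leave out the counting error of the other sum. Of the 30 gene lists fixed beforehand, the median log2 ratio of members with at least 20 UMIs is given, with a counting interval from 2000 Poisson resamples and a percentile among 10000 random lists matched on mean level. List members were counted as higher or lower at 2-fold, a rule of size. Of 565 symbols in the lists, 564 were in the files. Free RNA was the CPM of barcodes with 10 to 100 UMIs, 256869 UMIs in metastasis and 271390 in naive. A gene counted as above free RNA when its CPM, in the library where it was higher, was at least that of the same library's free RNA. Free RNA makes up only part of a cell's UMIs, so a gene that is not above it can still be expressed by the cells. Because most empty droplets had 100 to 300 UMIs (10901989 and 10697779 UMIs), that band was added as an alternative after seeing the data.

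Named genes followed a rule fixed before the data were examined. It named Timp1, Gfap, Vim, Lcn2, Serpina3n, Stat3, Cd44, Cd274 and Atp1b2 in astrocyte-like cells, and the 12 highest and 12 lowest log2 ratios there (with 10 CPM added to both values) among genes with at least 100 UMIs and above free RNA. It left out mitochondrial, ribosomal and unnamed predicted genes and markers of other classes. It named 4 highest and 4 lowest in each other class, and the members of each list with the largest ratios. Pmel was taken from a check of the record titles fixed beforehand.

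The interval of a ratio was tested on simulated Poisson counts drawn from the real means and totals with 200 changed genes. The interval itself assumes Poisson counts, so this checks the calculation only. It does not cover spread between cells, clusters or animals. In astrocyte-like cells, 96.4% of 10187 unchanged genes of 10387 lay inside, and 98% of 50 genes simulated at a log2 ratio of 1. Alternatives varied the limits on barcodes, doublets, resolution, naming, scaling, weighting, free RNA, depth, minimum UMIs and pseudocount. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and igraph 0.11.9 were used.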

Results

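The data were single-cell RNA counts from the brains of C57BL/6J mice that were 10 weeks old. One group, metastasis, had been injected intracranially with B16/F10-BrM, a mouse melanoma line, and the other, naive, had received no tumour cells according to its title. Each group was 1 library made from a pool of 3 brains and enriched with magnetic beads against ACSA-2, the antigen encoded by Atp1b2, to raise the share of astrocytes. The files held 89193669 UMIs in metastasis and 69445557 UMIs in naive, and 13340 and 13106 cells were kept, with medians of 2833 and 2764 UMIs per cell. There were no replicate libraries, so no difference could be set against the spread between animals and no test was made. Intervals are 95% intervals and cover counting error only. Log2 ratios are metastasis over naive throughout. The submitters exchanged the titles of both records after release, and the groups follow the titles now in use. The melanosome gene Pmel, which the injected cells express, had 174742 UMIs over all barcodes in metastasis and 4774 UMIs in naive.

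The first comparison asked which cell classes the enriched suspensions held with and without brain tumour. Macrophage/monocyte-like cells took 7.66% (7.22 to 8.13%) of kept cells in metastasis and 0.511% (0.396 to 0.649%) in naive, and melanoma-like cells took 5.38% (5.01 to 5.78%) and 0.137% (0.0814 to 0.217%). The size of the macrophage/monocyte-like share depended on the setting. With at most 10% mitochondrial UMIs it was 428 of 12514 cells in metastasis and 79 of 12493 in naive. No cluster took this name with at least 500 UMIs or at resolution 0.5. Astrocyte-like cells were the smaller share in metastasis, with 2.54% (2.28 to 2.82%) against 7.65% (7.20 to 8.12%) in naive, or 339 and 1003 cells. Oligodendrocyte-like cells were the largest class in both libraries, at 39.2% and 40.1%, and ependymal-like cells came next, at 17.9% (17.2 to 18.5%) and 24.5% (23.7 to 25.2%). Microglia-like cells took 7.46% (7.02 to 7.92%) in metastasis and 4.75% (4.39 to 5.12%) in naive. This direction turned with at most 10% mitochondrial UMIs, to 474 of 12514 cells in metastasis and 614 of 12493 in naive. It also turned at resolution 0.5, to 567 of 13340 and 624 of 13106, and without doublet removal. In each of these settings a cluster nearest to the microglia list, nearly all metastasis, went unnamed. The direction turned too with the limit on UMIs set from the deepest barcodes of each library. The microglia-like clusters there held 9 and 0 of 2643 cells in metastasis and 92 and 24 of 6811 in naive. An unnamed cluster of 624 cells in metastasis and 14 in naive was there nearest to the macrophage and monocyte list. Endothelial-like cells took 1.81% and 0.893%, choroid plexus epithelium-like cells 1.81% and 3.66%, and olfactory ensheathing-like cells 7.17% and 8.63%. The suspensions were enriched with ACSA-2 beads, so these shares do not measure the makeup of the brain. The astrocyte-like share of kept cells in metastasis (percent) was 5.81 and the astrocyte-like share of kept cells in naive (percent) was 11.7 when each cell was named by its own marker UMIs, and 0.265 and 4.14 when the limit on UMIs was set from the deepest barcodes of each library. That limit was 5378.4 UMIs in metastasis and 2769.92 UMIs in naive, so the libraries were not cut at the same depth. In the main setting, astrocyte-like cells had medians of 1654 and 1792 UMIs, below both limits.

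**Figure D1:**
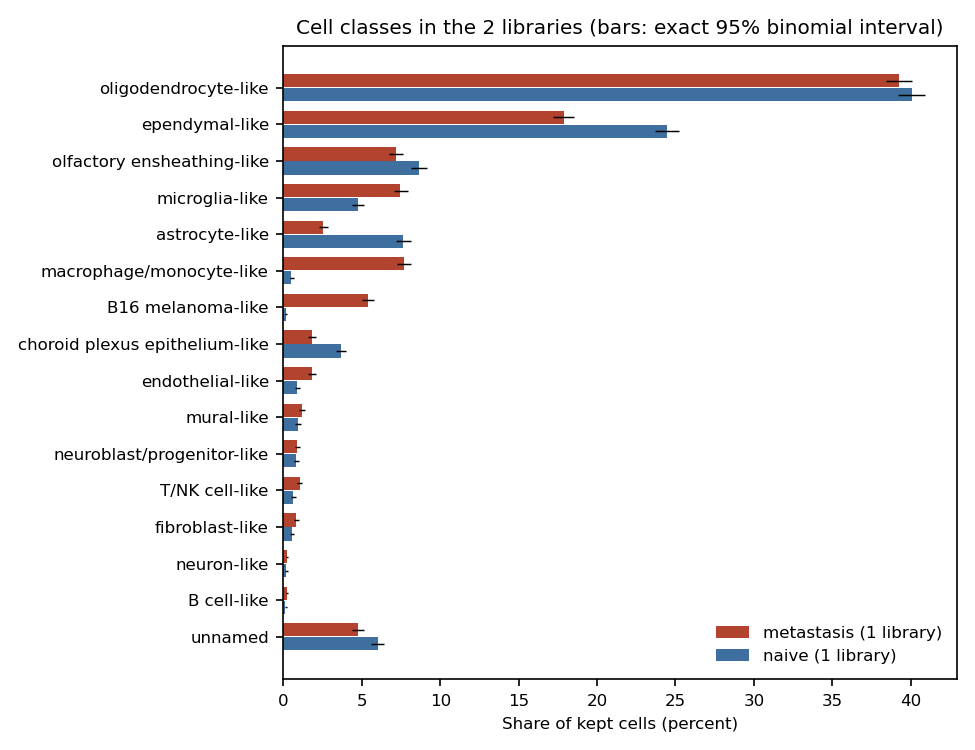
Share of kept cells (percent, horizontal axis) of each cell class in the metastasis library (red) and the naive library (blue), 1 library each. Black lines are exact 95% binomial intervals, which cover counting error only. Astrocyte-like cells took 2.54% in metastasis and 7.65% in naive, and macrophage/monocyte-like cells 7.66% and 0.511%. Shares are those of the main setting. Other settings gave other sizes, and some left no class named macrophage/monocyte-like.

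The second comparison, the one the study's title names, asked how astrocytes differ in brains with metastasis. In astrocyte-like cells, as named by cluster, the genes of normal astrocyte function differed by less than 2-fold. All 20 members of the homeostatic list, which holds glutamate transporters, water and potassium channels and gap junction proteins, lay within 2-fold, with a median log2 ratio of 0.03 (-0.01 to 0.08), at percentile 60.8 of 10000 random lists, a rank that describes these libraries only. The glutamate transporter gene Slc1a3 had 4118 CPM in metastasis and 3661 CPM in naive, a log2 ratio of 0.17 (0.10 to 0.24). Atp1b2, whose product the beads bind (ENSMUSG00000041329.13, chromosome 11, 69599736 to 69605942, minus strand), had 1008 CPM in metastasis and 1026 CPM in naive, a log2 ratio of -0.02 (-0.16 to 0.11). All 20 homeostatic members were above the level of free RNA, measured in barcodes with few UMIs. The median log2 ratio of homeostatic astrocyte in astrocyte-like cells was -0.43 with cells named by their own marker UMIs, -0.36 with cluster 17 added and -1.17 with the limit on UMIs from the deepest barcodes, which left 7 of these cells in metastasis.

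The reactive genes named beforehand were low in these cells. Of those with UMIs in both libraries, only Vim was higher in metastasis by more than counting error, and this turned with free RNA subtracted, where the log2 ratio of Vim in astrocyte-like cells was -0.25, at the melanoma and Ttr fractions of free RNA (-0.16) and with the limit on UMIs from the deepest barcodes (-0.22). Gfap, the main astrocyte intermediate filament (ENSMUSG00000020932.14, chromosome 11, 102887336 to 102900912, minus strand), had 45.3 CPM in metastasis and 30.6 CPM in naive, a log2 ratio of 0.57 (-0.13 to 1.23). Vim, which encodes vimentin (ENSMUSG00000026728.9, chromosome 2, 13573927 to 13582826, plus strand), had 160.3 CPM in metastasis and 114 CPM in naive, a log2 ratio of 0.49 (0.14 to 0.84), and its free RNA levels were 903 and 368 CPM. The transcription factor gene Stat3 (ENSMUSG00000004040.16, chromosome 11, 100885098 to 100939540, minus strand) had 42.1 CPM in metastasis and 35.1 CPM in naive, a log2 ratio of 0.26 (-0.45 to 0.93). Timp1, an inhibitor of metalloproteinases (ENSMUSG00000001131.11, chromosome X, 20870166 to 20874735, plus strand), had 2 and 2 UMIs, too few for a direction, with an interval of the log2 ratio of -2.10 to 5.48. Lcn2, a secreted iron-carrier protein of the acute phase (ENSMUSG00000026822.14, chromosome 2, 32384633 to 32388252, minus strand), had 4 and 0 UMIs. This was 4.30-fold higher with the 0 set to the floor of 3 UMIs over the class, leaving out the counting error of the 4 UMIs. Its 6.47 CPM in metastasis were below the 35.0 CPM of free RNA there. Serpina3n, a protease inhibitor (ENSMUSG00000021091.8, chromosome 12, 104406729 to 104414329, plus strand), had 8 and 11 UMIs, a log2 ratio of 1.23 (-0.29 to 2.68). Cd44, an adhesion receptor (ENSMUSG00000005087.17, chromosome 2, 102811141 to 102901665, minus strand), had 4 and 14 UMIs, with a log2 ratio of -0.12 (-2.18 to 1.55). Cd274, which encodes PD-L1 (ENSMUSG00000016496.7, chromosome 19, 29367455 to 29388095, plus strand), had 4 and 5 UMIs, with a log2 ratio of 1.37 (-0.97 to 3.58). Coordinates are those of GRCm38, and each span is the whole protein-coding gene. With each cell thinned to 1000 UMIs, Gfap was seen in 3.54% of astrocyte-like cells in metastasis and 2.19% in naive, against 1.57% and 0.800% of oligodendrocyte-like cells, which do not express it. Unthinned, the astrocyte-like shares were 6.78% and 4.69%. No kept cell had fewer than 1000 UMIs, so thinning left none out. Median depths were 1654 and 1792 UMIs in astrocyte-like cells and 2742 and 2984 UMIs in oligodendrocyte-like cells.

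Lists of inflammatory genes had higher medians in the astrocyte-like cells of the metastasis library, but most of their members stayed below the free RNA of the same library. Free RNA was a part of these cells' UMIs only, 0.102 by melanoma genes, 0.151 by Ttr and 0.201 by the median of marker lists. A level below free RNA can therefore still be the cells' own. Of the interferon response list, 13 of 26 members were measured and 6 were at least 2-fold higher, with a median of 0.84 (0.37 to 1.20), and 3 were above free RNA. Of the list of MHC class I and antigen processing, 9 of 16 were measured and 3 were at least 2-fold higher, with a median of 0.52 (0.35 to 1.06), and 0 were above free RNA. The MHC class I light chain gene B2m had 199 CPM in metastasis and 55.7 CPM in naive, a log2 ratio of 1.84 (1.46 to 2.22), beside free RNA levels of 997 and 114 CPM. Ifitm3, an interferon-induced membrane protein gene, had 191 CPM in metastasis and 55.7 CPM in naive, a log2 ratio of 1.78 (1.39 to 2.16), beside 938 and 413 CPM in free RNA. The pan-reactive list had 3 measured members of 13, all within 2-fold and below free RNA, with a median of 0.49 (-0.08 to 0.79). The list of STAT3 pathway and targets had 11 measured members, 3 at least 2-fold higher, and a median of 0.39 (0.14 to 0.84). Immediate early genes, which dissociation also induces, were at least 2-fold higher for 8 of 12 members, with 1 above free RNA. The melanoma marker list, which astrocytes do not express, had 6 measured members in the same cells and a median of 3.84 (3.33 to 4.12), and the microglia marker list a median of 0.81 (0.43 to 1.42). Free RNA was subtracted at the median fraction over marker lists, 0.201 in metastasis and 0.295 in naive. The median log2 ratio of interferon response in astrocyte-like cells was then -0.0387 and the median log2 ratio of MHC class I and antigen processing in astrocyte-like cells was 0.0373. At the melanoma fraction in metastasis and the Ttr fraction in naive, the interferon median was 0.30, so the result depends on the fraction used. With cells named by their own marker UMIs the interferon and MHC class I medians were 2.42 and 2.33 and the median log2 ratio of pan-reactive in astrocyte-like cells was 1.91. With cluster 17 added the 3 medians were 2.25, 1.83 and 2.06. The set named one by one took 169 of its 775 cells in metastasis and 127 of 1527 in naive from ependymal-like clusters, of which 61 and 0 came from cluster 10, led by interferon genes.

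Among the other lists in astrocyte-like cells, those of immune, proliferation and cytoskeleton genes had the higher medians, while those of matrix, glycolysis, hypoxia, metal and heat shock genes had medians from -0.12 to 0.31. Complement genes had 3 of 5 measured members at least 2-fold higher and a median of 1.92 (1.35 to 2.27), led by C1qb (2.29), C1qa (2.26) and C1qc (1.92), with 0 above free RNA. The A1-type reactive list had 2 of 4 measured members at least 2-fold higher and a median of 1.60 (1.10 to 2.29), led by Psmb8 (4.69) and H2-D1 (2.58), with 1 above free RNA. Chemokine and cytokine genes had 3 of 8 measured members at least 2-fold higher and a median of 0.77 (0.55 to 1.09), led by Ccl3 (3.47), Ccl12 (3.10) and Ccl4 (2.86), with 3 above free RNA. At the limit on UMIs from the deepest barcodes, with 7 cells left in metastasis, the median log2 ratio of chemokines and cytokines in astrocyte-like cells turned to -0.0473. MHC class II genes had 3 of 3 measured members at least 2-fold higher and a median of 3.86 (2.91 to 5.08), led by Cd74 (4.37), H2-Eb1 (3.86) and H2-Aa (3.34), with 0 above free RNA. Cytoskeleton genes had 4 of 15 measured members at least 2-fold higher and a median of 0.45 (0.21 to 0.67), led by Tmsb10 (2.20), Tagln2 and S100a11 (1.26), with 1 above free RNA. Immune modulator genes had 1 of 5 measured members at least 2-fold higher and a median of 0.46 (0.23 to 0.84), led by Lgals3 (1.90), Tgfb2 and Lgals1 (0.46), with 3 above free RNA. Proliferation genes had 1 of 5 measured members at least 2-fold higher and a median of 0.81 (0.28 to 1.09), with 0 above free RNA. With free RNA subtracted the median log2 ratio of proliferation in astrocyte-like cells was -0.81, and -0.22 with free RNA from barcodes of 100 to 300 UMIs, so its direction is not settled. Extracellular matrix genes had a median of 0.05 (-0.01 to 0.20), glycolysis genes 0.19 (-0.00 to 0.25), with Hk2 at 1.01 (-0.29 to 2.24), and hypoxia genes 0.31 (0.04 to 0.41). The median was -0.12 (-0.23 to 0.15) for metallothionein and metal genes, 0.19 (-0.16 to 0.48) for NF-kB targets, 0.09 (-0.04 to 0.23) for heat shock genes and 0.05 (-0.10 to 0.15) for neural stem and progenitor genes. The A2-type list had 2 measured members and no median is given. Y chromosome genes were present in both libraries, with Ddx3y at 79.3 CPM in metastasis and 103 CPM in naive.

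In astrocyte-like cells, genes below free RNA and markers of other classes were not eligible to be named by size. B2m and Ifitm3, left out for being below free RNA, had larger ratios than any gene given here. The genes that were named by size had small differences. The highest was Sfrp1, a secreted antagonist of Wnt signalling, with 97.1 CPM in metastasis and 34.1 CPM in naive and a log2 ratio of 1.51 (0.98 to 2.03). Dip2a had a log2 ratio of 1.30 (0.71 to 1.88) and Tgfb2, a transforming growth factor gene, 0.87 (0.45 to 1.28). The other higher genes were Rbm27 (0.88), Tox4 (0.89), Lpin1 (0.83), Pfkl (0.81), Cdh19 (0.78), Slc25a17 (0.83), Sema6a (0.83), Srpk1 (0.76) and Cbx6 (0.76). Among lower genes, Klhdc7a had a log2 ratio of -1.51 (-2.62 to -0.57) and the ephrin receptor gene Epha5 had 55.0 CPM in metastasis and 118 CPM in naive, a log2 ratio of -1.11 (-1.67 to -0.58). The others were Slc25a1 (-1.04), Gdpd2 (-1.06), Rnf14 (-1.03), Aifm3 (-0.87), Rgs6 (-0.94), Stau1 (-0.98), Cdk5rap2 (-0.92), Ccdc90b (-0.88), Cend1 (-0.91) and Diaph1 (-0.95). The limit on UMIs from the deepest barcodes left 7 astrocyte-like cells in metastasis and turned 6 of these directions, to 1.55 for Klhdc7a, 0.65 for Slc25a1, 0.14 for Gdpd2, 0.83 for Stau1, 1.31 for Cdk5rap2 and -0.56 for Cbx6. Cdk5rap2 also turned with cells named by their own UMIs (0.20) and Cbx6 with at least 2000 UMIs (-0.24). These 24 genes were the extremes of 2663 genes, so part of their size is selection among counting errors. Cholesterol synthesis genes lay within 2-fold for all 19 members, with a median of 0.03 (-0.08 to 0.20).

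The third comparison asked how the other classes caught with the astrocytes differed. Ependymal-like cells, the ciliated lining of the ventricles, had higher interferon and MHC class I genes in metastasis, by an amount that depends on which cells are given this name, and the gap to astrocyte-like cells was not tested. In the class as named here, 25 of 26 interferon response genes were at least 2-fold higher in metastasis, with a median of 3.00 (2.88 to 3.17), and 21 were above free RNA. The GTPase gene Iigp1 had 243 CPM in metastasis and 6.39 CPM in naive, a log2 ratio of 5.25 (4.94 to 5.59), and the ubiquitin-like Isg15 had a log2 ratio of 4.39 (4.16 to 4.63). Igtp, another interferon-induced GTPase gene, had a log2 ratio of 4.52 (4.25 to 4.80) and the chemokine gene Cxcl10 4.10 (3.87 to 4.33). Of the MHC class I and antigen processing list, 14 of 16 were at least 2-fold higher, with a median of 3.33 (3.27 to 3.57), and 12 were above free RNA. The pan-reactive list had 8 of 12 members at least 2-fold higher and a median of 2.78 (1.97 to 2.95). Lcn2 had 704 and 0 UMIs, at least 364-fold higher at a floor of 3 UMIs over the class, and Serpina3n had 533 and 36 UMIs, a log2 ratio of 4.52 (4.03 to 5.05). Gfap had 197 CPM in metastasis and 61.3 CPM in naive, a log2 ratio of 1.68 (1.56 to 1.81). Timp1 had 19 and 2 UMIs, a log2 ratio of 3.88 (1.83 to 7.03), but its level in metastasis was below the 27.3 CPM of free RNA there. Complement genes were at least 2-fold higher for 8 of 10 members, with C4b at 3.79 (3.56 to 4.04), and 5 were above free RNA. The complement list holds the microglial genes C1qa, C1qb and C1qc, and microglia markers had a median of 1.01 (0.86 to 1.47) in these cells and macrophage and monocyte markers 4.86 (3.86 to 5.16), with 1 and 0 above free RNA. Immediate early genes, which dissociation also induces, were at least 2-fold higher for 5 of 16, with a median of 0.82 (0.70 to 0.92) and 6 above free RNA. Lower genes were Ucma (-1.32, interval -1.43 to -1.21), Tmem267 (-1.30), Htr5b and Mrln (-0.76). The homeostatic astrocyte list had a median of 0.01 (-0.06 to 0.05) in these cells. Different clusters held the class in the libraries. In metastasis cluster 10, led by the interferon and complement genes Ifit3, Gbp2, Igtp and C3, gave 992 of 2383 cells. In naive it gave 23 of 3205, and clusters 2 and 3 gave 1212 and 1203. Without cluster 10 the median log2 ratio of interferon response in ependymal-like cells was 1.29, and it was 1.28 with at least 500 UMIs, 0.88 with at least 2000 UMIs, 1.17 without doublet removal and 1.22 at resolution 2, where the cells of cluster 10 went unnamed. At 500 UMIs the median log2 ratio of interferon response in astrocyte-like cells was 1.21. Without cluster 10 the median log2 ratio of MHC class I and antigen processing in ependymal-like cells was 1.84.

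**Figure D2:**
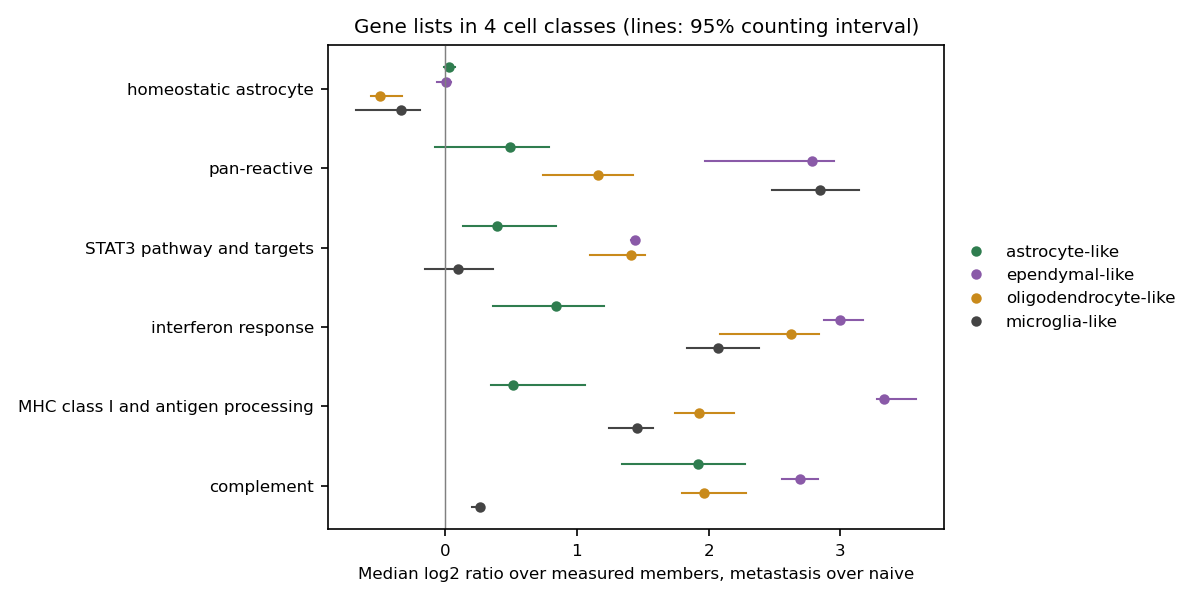
Median log2 ratio of metastasis over naive (horizontal axis) of 6 gene lists (vertical axis) in astrocyte-like (green), ependymal-like (purple), oligodendrocyte-like (orange) and microglia-like (dark grey) cells, 1 library per group. Points are medians over measured members and lines are 95% counting intervals. The interferon response median was 0.84 in astrocyte-like and 3.00 in ependymal-like cells.

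Microglia-like cells had lower levels of homeostatic genes and higher levels of disease-associated and MHC class II genes in metastasis. Of the homeostatic list, 12 of 14 members were at least 2-fold lower, with a median of -1.38 (-1.49 to -1.26). The median of all genes with at least 100 UMIs in this class was -0.22, and relative to it the homeostatic median was -1.16. The purinergic receptor gene P2ry12 had 561 CPM in metastasis and 2161 CPM in naive, a log2 ratio of -1.95 (-2.03 to -1.86), and Tmem119 had a log2 ratio of -1.73 (-1.83 to -1.62). Of the disease-associated list, 14 of 21 members were at least 2-fold higher, with a median of 1.82 (1.68 to 2.21), or 2.04 relative to all genes. The lipid carrier gene Apoe had a log2 ratio of 4.63 (4.58 to 4.68), Gpnmb 5.66 (4.73 to 6.80) and the lipoprotein lipase gene Lpl 4.40 (3.89 to 4.96). MHC class II genes were at least 2-fold higher for 5 of 7 members, with H2-Aa at 6.05 (5.12 to 7.18) and a median of 5.02 (4.45 to 5.41). This direction turned at the limit on UMIs from the deepest barcodes, where the median log2 ratio of MHC class II in microglia-like cells was -0.0830, and the median was 3.01 without cluster 14. The oxidase gene Cybb had a log2 ratio of 6.62 (5.07 to 8.90). The interferon response list had 20 of 26 members at least 2-fold higher. The chemokine gene Cxcl9 had 1249 and 0 UMIs, at least 144-fold higher at a floor of 3 UMIs. The genes lowest by size were Upk1b (-2.81), Csmd3 (-2.37), Hspb1 (-2.19) and Slc2a5 (-2.14). In metastasis cluster 14, led by the chemokine genes Ccl12 and Ccl4 with C1qa and Lpl, gave 524 of 995 cells, and in naive cluster 6 gave 615 of 622. Markers of macrophages and monocytes were also higher in this class, at least 2-fold for 6 of 7 with a median of 2.74 (2.20 to 4.27) and Ms4a7 and Lyz2 among the leading genes, and dendritic cell markers had a median of 3.52 (2.98 to 4.37). Erythrocyte markers were higher for 4 of 5 with a median of 2.63 (2.37 to 3.08) and 4 above free RNA. Markers of ependymal cells (-1.23 (-1.41 to -0.97), 8 of 10 at least 2-fold lower) and choroid plexus (-1.18 (-1.53 to -0.78), 5 of 9) were lower, with 0 above free RNA, and immediate early genes had a median of -0.56 (-0.64 to -0.45). For interferon and MHC class I genes, free RNA would have to be a fraction of 1.64 (1.61 to 1.67) of these cells' UMIs, more than all of them. The fraction measured was 0.0667 from melanoma genes, 0.0814 from Ttr and 0.244 from the median of marker lists. This calculation, chosen after seeing the data, argues against free RNA as the whole cause for those genes. Cells of other types within the class were not tested for. The size of the homeostatic difference depended on the choice of cells. The median log2 ratio of microglia homeostatic in microglia-like cells was -0.31 without cluster 14, -0.26 at 10% mitochondrial UMIs, -0.47 without doublet removal, -0.59 at resolution 0.5 and -0.69 with at least 500 UMIs. Without cluster 14 the median log2 ratio of microglia disease-associated in microglia-like cells was 0.81.

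Oligodendrocyte-like cells kept their myelin genes at the same level and had more Serpina3n in metastasis. All 13 members of the myelin list lay within 2-fold, with a median of 0.02 (-0.00 to 0.03). Serpina3n had 33.5 CPM in metastasis and 8.30 CPM in naive, a log2 ratio of 2.01 (1.75 to 2.29), above its free RNA levels of 11.7 and 0 CPM. Clgn (0.96, interval 0.78 to 1.15), Mgst3 (0.81, interval 0.72 to 0.90) and Hopx (0.77, interval 0.71 to 0.83) were higher, and Gstp1 (-0.91, interval -1.03 to -0.79), Gstp-ps (-0.67), Srgap1 (-0.55) and the prostaglandin D synthase gene Ptgds (-0.53) were lower. Gstp1 and Gstp-ps are near-identical copies between which reads can be split, so each of these values is uncertain. The list of oligodendrocyte reactive genes had 6 of 12 members at least 2-fold higher and a median of 1.07 (0.95 to 1.16), with 5 above free RNA. The interferon response list had a median of 2.63 (2.08 to 2.84), but 2 of its 26 members were above free RNA. Markers that these cells do not express were higher as well, with medians of 3.13 (2.84 to 3.96) for macrophages and monocytes, 0.67 (0.52 to 0.86) for microglia and 3.46 (3.08 to 3.82) for melanoma, with 0, 1 and 0 members above free RNA, and astrocyte markers were lower (-0.51, interval -0.61 to -0.41). Hopx, Mgst3 and Clgn are leading genes of cluster 12, which held 3.68% of kept cells in metastasis and 1.81% in naive, so their ratios also carry the share of that cluster. Cluster 15, led by the stress genes Fos and Fosb, was part of this class, and immediate early genes, which dissociation also induces, were at least 2-fold higher for 9 of 17 with a median of 0.97 relative to all genes and 2 above free RNA.

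Endothelial-like cells had lower levels of blood-brain barrier genes and higher levels of proliferation genes in metastasis. All 14 measured barrier genes were at least 2-fold lower, with a median of -2.74 (-2.83 to -2.55), or -2.86 relative to the median of all genes, 0.12. The transporter gene Slco1a4 had 154 CPM in metastasis and 1987 CPM in naive, a log2 ratio of -3.69 (-3.86 to -3.52), and the tight junction gene Cldn5 had a log2 ratio of -2.83 (-2.90 to -2.76). Proliferation genes were at least 2-fold higher for 18 of 20 members, and the topoisomerase gene Top2a had 1180 and 0 UMIs, at least 48.9-fold higher, and the replication gene Pclaf 1782 and 0 UMIs, at least 73.9-fold higher. Plvap, a component of the diaphragms of fenestrated vessels, had 1338 and 0 UMIs, at least 55.5-fold higher, each at the floor of 3 UMIs over the class. Igfbp3 had a log2 ratio of 6.14 (5.36 to 7.05), and the chemokine gene Cxcl12 -3.77 (-3.89 to -3.64). Sema3c (-4.01) and Spock2 (-3.86) were also lower, and 9 of 14 endothelial activation genes were at least 2-fold higher. Endothelial markers, which share genes such as Slco1a4 and Cldn5 with the barrier list, were lower for 7 of 12, with a median of -1.59 (-1.73 to -1.43). Mural markers (-0.75, interval -0.95 to -0.41) and erythrocyte markers (-3.68 (-4.08 to -3.59), 5 of 6 lower) were lower too, with 11 and 5 members above free RNA. The interferon response list was lower as well, with 15 of 26 members at least 2-fold lower and a median of -1.13 (-1.30 to -0.91), or -1.25 relative to all genes. Cluster 24, led by Igfbp3, Cd93 and Plvap, gave 185 of 242 cells in metastasis and 1 in naive. Cluster 26 gave 57 cells in metastasis and 116 of 117 in naive. The class was thus a different mix of clusters in each library, which all these ratios carry. Cluster 26 was not compared alone.

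Mural-like cells, which surround vessels, also had higher proliferation genes, with 19 of 20 members at least 2-fold higher, and higher levels of part of the matrix genes. Col4a1, a basement membrane collagen gene, had 2737 CPM in metastasis and 387 CPM in naive, a log2 ratio of 2.82 (2.57 to 3.08), and Ccl2 had a log2 ratio of 6.63 (4.77 to 9.68). The contractile cell gene Pln had a log2 ratio of -3.80 (-4.31 to -3.32). Pclaf (6.46, interval 4.60 to 9.51) was higher, as were the collagen genes Col15a1 with 285 and 0 UMIs, at least 34.1-fold, and Col6a3 with 265 and 0 UMIs, at least 31.7-fold at the floor of 3 UMIs over the class, and Sncg (-3.28), Rcan2 (-2.78) and Sparcl1 (-2.48) were lower. The median of all genes in this class was 0.35, and relative to it the extracellular matrix list had a median of 1.36, with 8 of 15 members at least 2-fold higher and 2 lower. Fibroblast markers were higher in this class for 3 of 5, led by Col1a1, Col3a1 and Col1a2, with a median of 2.02 (1.60 to 2.77) or 1.67 relative to all genes and 4 above free RNA. Immediate early genes were at least 2-fold lower for 11 of 16, with a median of -1.38 (-1.54 to -1.21). Cluster 31, led by Rgs5, Cd248 and Anxa1, gave 95 of 158 cells in metastasis and 0 in naive, where cluster 29 gave 71 of 120.

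Macrophage/monocyte-like cells, of which naive held 67, had lower MHC class II genes in metastasis, opposite to microglia-like cells, although the difference between the classes was not tested. All 7 class II genes were at least 2-fold lower, with a median of -2.14 (-2.37 to -2.08). The dendritic cell markers Cd209a (-5.49, interval -6.51 to -4.50) and Siglech (-3.78, interval -4.40 to -3.14), the latter also a microglia marker, were lower with them. So were the B cell markers Cd79b (-2.19, interval -2.97 to -1.31) and Ighm (-1.88, interval -2.39 to -1.34). Of the class's own markers, not all given here, Lyve1 (-3.35, interval -4.60 to -1.90), Cd163 (-3.25, interval -4.24 to -2.15) and Ccr2 (-2.70, interval -3.09 to -2.29) were lower. A different mix of cells in the naive class is therefore left open. Immediate early genes were at least 2-fold lower for 11 of 17, with a median of -1.12 (-1.32 to -0.99) and 17 above free RNA, and the heat shock list for 5 of 16, with a median of -0.33 (-0.52 to -0.21), so handling of the suspensions is left open too. The lectin gene Mgl2 had 13.3 CPM in metastasis and 508 CPM in naive, a log2 ratio of -5.25 (-5.70 to -4.81). Spp1, which encodes osteopontin, had a log2 ratio of 5.44 (4.60 to 6.44) and Gpnmb 4.52 (3.64 to 5.58). Saa3, an acute phase gene, had 2145 and 0 UMIs, at least 19.6-fold higher at the floor of 3 UMIs. The heat shock genes Hspa1b (-3.94, interval -4.11 to -3.76) and Hspa1a (-3.50, interval -3.64 to -3.37) and the prostaglandin dehydrogenase gene Hpgd (-3.59) were lower, and the chemokine gene Cxcl9 (6.35, interval 4.50 to 9.40) was higher.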

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

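All 3 tests of the 18 melanoma-like cells in the naive library, whose animals received no tumour cells by the record title, were chosen after the cells had been seen. Barcodes shared with the metastasis library are argued against, since the same barcodes held 0% as many UMIs of Pmel, Mlana, Tyrp1 and Dct there (12126 UMIs in naive against 0). Free RNA is argued against too, because these genes took 60.6 times their share in the free RNA of the naive library, and the cells had a median of 31699.5 UMIs against 29281 UMIs in metastasis. Whole cells of the metastasis suspension reaching the naive library stay open: the naive cells were 2.51% of the number in metastasis for melanoma-like cells and 1.73% for clusters 10, 14, 24 and 31, which are nearly all metastasis, the latter over the former being 0.689 with a counting interval of 0.373 to 1.31. Mixing may have happened at any step before the droplets were made, and no biological explanation was tested.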

How the results depend on the processing

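The alternatives that added cluster 17, left out clusters 10 or 14, left melanoma and myeloid cells out of the total, took free RNA from the 100 to 300 UMI band or at the melanoma and Ttr fractions, and all alternatives for ependymal-like and microglia-like cells were chosen after seeing the data. Results are the astrocyte-like share of kept cells in metastasis (percent), the astrocyte-like share of kept cells in naive (percent), the median log2 ratio of pan-reactive in astrocyte-like cells, the median log2 ratio of homeostatic astrocyte in astrocyte-like cells, the median log2 ratio of MHC class I and antigen processing in astrocyte-like cells, the median log2 ratio of interferon response in astrocyte-like cells, the median log2 ratio of interferon response in ependymal-like cells and the median log2 ratio of microglia homeostatic in microglia-like cells, called below the shares, pan-reactive, homeostatic, MHC class I, interferon, ependymal interferon and microglia medians. With at least 500 UMIs and 300 genes the shares were 2.98% and 8.16%, the interferon median 1.21, the ependymal interferon median 1.28 and the microglia median -0.69. With at least 2000 UMIs and 1000 genes the shares were 1.18% and 4.75%, the homeostatic median 0.0877 and the ependymal interferon median 0.88. With the limit from the 99th percentile, which left 7 and 282 astrocyte-like cells, the shares were 0.265% and 4.14%, and the pan-reactive, homeostatic and interferon medians 1.09, -1.17 and 1.56. This limit differed between the libraries, at 5378.4 UMIs in metastasis and 2769.92 UMIs in naive. At most 10% mitochondrial UMIs gave a homeostatic median of 0.12 and a microglia median of -0.26. Without doublet removal the ependymal interferon and microglia medians were 1.17 and -0.47. Leiden resolution 0.5 gave a microglia median of -0.59 and resolution 2 an ependymal interferon median of 1.22. With cells named by their own marker UMIs the shares were 5.81% and 11.7%, and the pan-reactive, homeostatic, MHC class I, interferon and microglia medians 1.91, -0.43, 2.33, 2.42 and -1.62. With cluster 17 added the shares were 3.75% and 9.55%, and the first 4 of these medians 2.06, -0.36, 1.83 and 2.25. Without melanoma and myeloid cells in the total the share in metastasis was 2.97%. With free RNA subtracted the homeostatic, MHC class I, interferon and ependymal interferon medians were -0.0249, 0.0373, -0.0387 and 3.35. With the 100 to 300 UMI band the MHC class I and interferon medians were -0.16 and -0.0395, and at the melanoma and Ttr fractions the interferon median was 0.30. With no minimum of UMIs they were 1.27 and 1.47, and at least 100 UMIs gave an MHC class I median of 1.34. Thinning gave an ependymal interferon median of 3.47 and a microglia median of -0.83. Centring gave a microglia median of -1.16, the mean per cell -0.88 and leaving out cluster 14 -0.31. Leaving out cluster 10 gave an ependymal interferon median of 1.29. With 500 or 2000 UMIs, no doublet removal and resolution 2, the cells like cluster 10 had gone unnamed because the neuroblast marker Cd24a was among their 10 leading genes and no ependymal marker was.

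Other directions also turned. The median log2 ratio of chemokines and cytokines in astrocyte-like cells was -0.0473 at the 99th percentile limit. The median log2 ratio of proliferation in astrocyte-like cells was -0.81 with free RNA subtracted and -0.22 with the 100 to 300 UMI band, where the median log2 ratio of microglia disease-associated in astrocyte-like cells was -0.16. The median log2 ratio of oligodendrocyte reactive in astrocyte-like cells was -0.17 and -0.0316 under the same pair of settings. The median log2 ratio of myelin and its lipids in astrocyte-like cells was -0.41 and -0.43 with 500 and 2000 UMIs, -0.88 at 10% mitochondrial UMIs, -0.0373 without doublet removal and -0.0436 with cells named by their own UMIs. The log2 ratio of Vim in astrocyte-like cells was -0.22 at the 99th percentile limit, -0.25 with free RNA subtracted and -0.16 at the melanoma and Ttr fractions. Cbx6 was -0.24 with 2000 UMIs, and at the 99th percentile limit Cbx6 was -0.56, Klhdc7a 1.55, Slc25a1 0.65, Gdpd2 0.14, Stau1 0.83 and Cdk5rap2 1.31. Cdk5rap2 was 0.20 with cells named by their own UMIs, and the median log2 ratio of MHC class II in microglia-like cells was -0.0830 at the 99th percentile limit. Apart from the free RNA and cluster settings, the cause was not tested. Values for single genes held in 460 cases and moved without turning in 32, and those of other lists held in 440 and moved in 148. The pan-reactive list had too few members left for a value with free RNA subtracted, thinned cells or at least 100 UMIs. No paired analysis was possible because each group is 1 library, and for the same reason no replicate could be left out.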

Other observations

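The tests of the interferon and MHC class I patterns in astrocyte-like and ependymal-like cells were chosen after the results had been seen. Choroid plexus epithelium-like cells had more Lcn2 in metastasis, with 220 and 2 UMIs and a log2 ratio of 7.84 (5.97 to 10.90), and more Dlk1 (2.20, interval 1.75 to 2.68), Axin1 (1.38) and Lgals3bp (0.81). Lower there were Cxcl12 (-1.28), Rn7sk (-1.24), Gabra4 (-1.01) and Epha4 (-0.66), beside a median of all genes of 0.11. T/NK cell-like cells had more of the cytotoxic granule gene Gzmb, at 1.68 (1.05 to 2.37), more Ly6a (1.32), Ccl4 (1.27) and Ldha (1.22), and less of the cytokine gene Il17a, at -3.54 (-4.40 to -2.78), and of Hspa1b (-2.11), Hspa1a (-1.83) and Txnip (-1.20). Fibroblast-like cells had 17 of 22 interferon response genes at least 2-fold higher, 21 of the measured members were above free RNA, and Gbp2 had a log2 ratio of 4.27 (3.12 to 5.73). There the chemokine genes Cxcl10 (6.26, interval 4.40 to 9.32) and Ccl2 (5.85, interval 3.98 to 8.91) were higher, Ccl7 had 138 and 0 UMIs, at least 26.2-fold higher at the floor, and Fmod (-1.57, interval -2.11 to -1.05), Sh3bgrl (-0.86), Ash1l (-0.86) and Clec3b (-0.85) were lower. Erythrocyte markers were lower in this class for 4 of 5 (-8.54, interval -9.34 to -7.43) and endothelial markers higher for 2 of 4 (1.64, interval 0.84 to 2.23), so a different mix of cells is left open. Olfactory ensheathing-like cells had 7 of 26 interferon genes at least 2-fold higher, with a median of 0.50 (0.42 to 0.73) and 11 above free RNA. Macrophage and monocyte markers (3.59, interval 2.86 to 3.96), microglia markers (0.74, interval 0.49 to 1.21) and oligodendrocyte markers (0.81, interval 0.71 to 0.91) were higher there, with 0, 1 and 2 above free RNA, and 4 of 5 neutrophil markers were at least 2-fold lower, led by S100a8 and S100a9. There H2-T23 (1.45), Shtn1 (1.26), Phyhipl (1.11) and Trim59 (1.01) were higher, and Nr1d1 (-1.07), Slc2a13 (-0.92), Slc19a1 (-0.86) and Mfsd11 (-0.85) lower. Neuroblast-like cells had all 20 proliferation genes within 2-fold. Their Hmgcs1 (0.78), Cul3 (0.80), Hspa4l (0.77) and Hnrnph2 (0.77) were higher, and Zfp451 (-0.88), Zfp704 (-0.86), Btg1 (-0.83) and AC160336.1 (-0.80) lower.

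Cluster 17, kept out of the astrocyte-like class, held cells that were named astrocyte by their own marker UMIs, 111 in metastasis and 201 in naive, a set chosen after seeing the data. In these cells Gfap had 376 and 147 CPM, a log2 ratio of 1.36 (0.86 to 1.87), above free RNA levels of 85.6 and 51.6 CPM. Vim had 1279.5 and 376 CPM, a log2 ratio of 1.77, beside 903 and 368 CPM in free RNA, and Lcn2 had 33 and 0 UMIs. Epcam (18 and 1 UMIs) and Six3 (1.53) were higher too. Of the astrocyte markers, Gja1 (-0.73) and Slc1a2 (-0.41) were lower, Aqp4 was higher (0.88, interval 0.25 to 1.52) and Slc1a3 differed little (-0.11, interval -0.25 to 0.04). A different mix of cells is not excluded. In the whole cluster the pituitary hormone gene Cga had 949 and 46.9 CPM, so it also holds other cells. Of all cells named astrocyte in this way, 334 of 775 in metastasis and 992 of 1527 in naive lay in the astrocyte-like clusters.

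Interferon and MHC class I genes were higher in astrocyte-like cells of the metastasis library. Free RNA would have to make up a fraction of 0.160 (0.142 to 0.180) of their UMIs to give this alone. The fraction measured in the same cells was 0.102 from melanoma genes, 0.151 from Ttr and 0.201 from the median of marker lists, on both sides of the value needed. With free RNA from barcodes of 100 to 300 UMIs, 0.155 (0.138 to 0.172) was needed. Melanoma genes then gave 0.119 and Ttr 0.114, both below that interval, and the median of marker lists gave 0.213, above it. Those medians include lists above 1, which free RNA cannot give, 2 of 15 in the first band and 3 of 18 in the second. Free RNA and expression by these cells therefore cannot be told apart, and a response of astrocytes to the tumour stays open and untested.

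The same genes were higher in ependymal-like cells, and for the class with cluster 10 the tables argue against free RNA as the whole cause. With cluster 10, free RNA would have to be a fraction of 1.38 (1.37 to 1.39), more than all of their RNA. Without cluster 10 it would have to be 0.313 (0.303 to 0.323). The fraction measured was 0.0608 from melanoma genes, 0.0857 from Ttr and 0.222 from the median of 15 marker lists. Single lists gave 0.125 for microglia, but 0.330 for oligodendrocyte and 0.664 for mural markers. Of the 15 lists, 6 reached 0.303. Of these, 3 were above 1, which free RNA cannot give, so a list can also carry the cells' own expression. The measured fractions lay on both sides of the value needed. Without cluster 10, free RNA and expression by these cells therefore cannot be told apart. Microglia-like cells caught with cluster 10 would have to give 22.5% of its RNA to bring its B2m. C1qa, C1qb, C1qc, Tyrobp and Fcer1g reached a fraction of 0.00527 of the excess this would bring (0.00188 to 0.00876). These values argue against microglia in cluster 10, and the other clusters were not measured. The levels of macrophage/monocyte-like cells were not used, so macrophages caught with the cells were not tested. A response of ependymal cells to the tumour is a hypothesis left open, found and tested on the same 2 libraries, and handling of the suspensions was not tested, although immediate early genes, which dissociation also induces, were higher in the same cells (median log2 ratio 0.82 (0.70 to 0.92)).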
